A study of Homo sapiens with 8 samples.

How the data were processed

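The study measured RNA in 8 pediatric ependymomas, tumours of the brain and spinal cord that resemble the ciliated lining of the ventricles. Per the labels, 5 tumours came from the posterior fossa, the compartment of the cerebellum and brainstem, and had low global H3K27me3, a histone mark of Polycomb repression; they are called PF1, PF3, PF4, PF13 and PF14. The other 3 came from above the tentorium, had high H3K27me3, and are called ST1, ST2 and ST3. Location and H3K27me3 status divide the tumours the same way, so each difference between the groups may belong to either, and no covariate could be fitted. The labels name no batch and do not state whether any tumours share a donor, so p-values measure the spread between these tumours.

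Per the labels' protocols, the authors extracted total RNA with Trizol, treated it with DNase, prepared libraries by an Illumina TruSeq protocol and sequenced them on a HiSeq 2000. Whether poly(A) RNA was selected is not given in the sources used here. The submitters' processing notes name TopHat2 2.0.3, an aligner, and HTSeq 0.5.3p3, a read counter, with the genome builds hg19 and GRCh37. The annotation release, the strand setting and any filter are not given in the sources used here. The deposited values are raw read counts per Ensembl gene, with 1 column per tumour and no normalization, in 65248 genes. Of their identifiers, 56322 were paired with a symbol through a table of gene names and 56813 occur in GENCODE release 29. Coordinates are those of GENCODE 29 on GRCh38, found by gene identifier, and none was taken from the deposited counts. Reads from overlapping genes, from a gene and its antisense partner, or from near-identical copies could not be told apart, and values of such genes are uncertain.

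Library totals ran from 31762491 to 46912822 counts, and a count of 3 corresponded to 0.0639 to 0.0945 CPM, the unit of counts scaled to library size. A chi-square comparison of gene counts found no pair of libraries that agreed within sampling noise. Intervals on count ratios have a confidence level of 95% and cover counting error only, since reads were counted without molecular identifiers.

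The main comparison used edgeR 4.0.16 in R 4.3.3, with TMM scaling, the filterByExpr filter with the group, and the quasi-likelihood F test on all 8 tumours. Benjamini-Hochberg adjusted p-values under 0.05 were called, over 31458 tested genes. Fold changes are log2 of PF over ST, and the standard error (SE) of each is its size divided by the square root of F. CPM values are TMM-scaled and are given as mean ± SD. The biological coefficient of variation was 70.9%, and 54.7% without PF14.

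The gene lists, 38 in all, were fixed together with the tests, the groups, the alternatives and the rule for named genes before the data were examined. They cover Polycomb and DNA methylation machinery, Polycomb targets, brain regions, HOX genes, tumour types, cell types, signalling, matrix, other processes and library quality. The 37 lists with at least 3 tested members were tested with limma's camera (limma 3.58.1) at its preset correlation of 0.01. Camera with an estimated correlation and fry, which asks whether the genes of a list move on balance in 1 direction, were the alternatives. Each list also has a score per tumour, the mean log2 CPM of its tested members with a prior count of 2. Scores were compared by an exact two-sided permutation test over the 56 splits of 8 tumours into 5 and 3, where the smallest possible p is 0.0357. Python 3.11.15 with SciPy 1.17.1 computed these.

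Named genes were of 3 kinds. The first were up to 10 genes per direction with the largest fold among those called, with an average log2 CPM of at least 1, no overlap between the groups and an established symbol; 8 genes higher in PF and 10 lower met this. The second were up to 4 called members of each list with the smallest adjusted p, or the 2 with the highest mean CPM where none was called. The third were 14 genes of the Polycomb, DNA methylation and tumour-type questions, named whatever their values. The same rule was applied later to the tumours without PF14. AQP4, GABRA6, CBLN3, FAT2 and the genes that open the other observations were chosen after their values were seen. Genes of the Y chromosome and the X-inactivation transcript were not reported here. Some other genes are not reported here either, and the test of the group of PF13 was changed at the end to use 4 forebrain genes named in the report.

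The edgeR comparison was tested on simulated counts drawn from the means and library sizes of these tumours, with 50 genes changed at each size. Only genes with a mean of at least 1 CPM were changed, so recovery is not known for genes below that. Each gene was drawn independently, so no simulated library departed from the others in many genes at once, as PF14 does. For 5 PF against 3 ST tumours it recovered 6% of genes changed by 2 on the log2 scale, 56% of those changed by 4, 92% by 6 and 94% by 8, and called 7 unchanged genes of 30610 in that step. For 4 PF against 3 ST tumours it recovered 16%, 90%, 94% and 96%, and called 12 unchanged genes of 30211.

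Alternatives were RLE and upper-quartile scaling, library size alone, DESeq2 1.42.0, limma voom with and without sample quality weights, robust edgeR estimation, other filters and thresholds, removal of mitochondrial, histone, hemoglobin and ribosomal protein genes, a block on the tumour number, and each tumour left out in turn. PF14 stood apart from the others once the data were seen. All results were therefore also computed without PF14, and some without PF13 and PF14; the leave-one-out comparison itself was planned, its use beside each result was not. The median log2 fold change of all tested genes was 0.12 with TMM scaling and moved by -0.18 with library size alone, so fold changes are relative to TMM scaling.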

Results

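RNA was counted per gene in 8 pediatric ependymomas. The 5 posterior fossa tumours had low global H3K27me3, a histone mark laid down by Polycomb repressive complex 2 (PRC2), and the 3 supratentorial tumours had high H3K27me3. The series concerns the loss of this mark and of DNA methylation in posterior fossa ependymoma, so the comparison asks which transcripts differ between the groups. Total counts were 46912822, 31762491, 37567072, 36698473 and 37585798 in PF1, PF3, PF4, PF13 and PF14, and 36795561, 43700705 and 39885731 in ST1, ST2 and ST3. The mitochondrial ribosomal RNA genes took 11.1% to 24.95% of the counts of a library.

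PF14 differed from the other posterior fossa tumours in many cell type markers. GFAP, the astrocyte filament protein, stood at 5.61 CPM in PF14 and between 1160 and 20300 CPM in PF1, PF3, PF4 and PF13. Its myeloid, lymphocyte and stroma scores were 7.50, 4.35 and 8.85, against at most 4.10, -0.05 and 7.01 in the other 7 tumours. PF13 held neuronal transcripts, with a cerebellar neuron score of 4.63 against at most 1.78 in the other 7 tumours. Rank correlations of log2 CPM ran from 0.859 to 0.938 among PF1, PF3, PF4 and PF13 and from 0.918 to 0.940 among the supratentorial tumours. Between these sets they ran from 0.823 to 0.896. PF14 correlated at 0.718 to 0.778 with the other posterior fossa tumours and at 0.774 to 0.795 with the supratentorial tumours. The first principal component held 45.9% of the variance, with PF14 at 140.9 and the other tumours between -64.8 and 21.8. On the second, with 28.8%, the supratentorial tumours lay between -65.7 and -47.6 and the posterior fossa tumours between -10.8 and 65.7. On the third, with 9.7%, PF13 lay at -68.1.

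**Figure D1:**
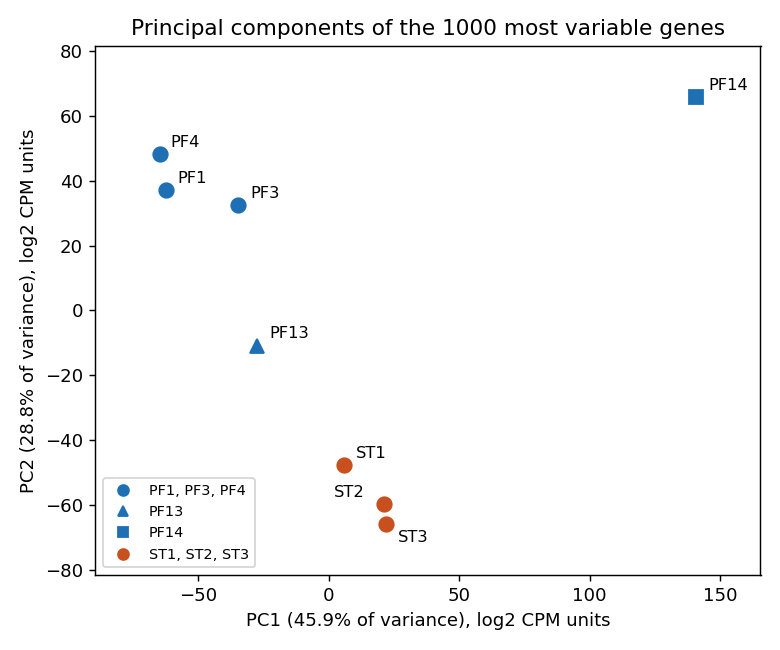
Principal components of log2 CPM of the 1000 most variable genes, 1 point per tumour; the horizontal axis is the first component and the vertical axis the second, both in log2 CPM units. PF14 lies at 140.9 on the first component, and the 3 supratentorial tumours lie between -65.7 and -47.6 on the second.

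IRX1, an Iroquois homeobox transcription factor, AQP1, a water channel, and TFCP2L1, a transcription factor of epithelia, were higher in posterior fossa tumours. IRX1 was at 13 ± 7.3 CPM (SD, n = 5) against 0.0232 ± 0.0244 CPM (SD, n = 3), and AQP1 at 524 ± 273 against 7.47 ± 2.96 CPM. TFCP2L1 was at 78.1 ± 36.3 against 1.23 ± 0.613 CPM. HES3, a repressor of the HES family, NR2E1, a transcription factor of the forebrain, and FBP2, a gluconeogenic enzyme, were lower. HES3 had 2 counts in the 5 posterior fossa tumours together and 3242 in the 3 supratentorial ones, a ratio of 2240 (95% counting interval 620 to 18500).

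In the edgeR test on all 8 tumours 12 of 31458 genes were higher and 105 lower in posterior fossa tumours, of which 9 and 65 were protein-coding. The log2 fold change of IRX1 was 8.95 ± 1.39 (SE; edgeR adjusted p = 0.0442), with 2393 counts against 3, a ratio of 577 (95% counting interval 197 to 2800). AQP1 had a log2 fold change of 6.13 ± 0.78 (edgeR adjusted p = 0.026) and TFCP2L1 of 5.99 ± 0.75 (edgeR adjusted p = 0.0243). DMKN, a secreted protein of epidermis, RCAN3, a regulator of calcineurin, and GFPT2, an enzyme of hexosamine synthesis, were higher by 5.34 ± 0.86, 4.39 ± 0.68 and 3.78 ± 0.59. PDE3B, a cyclic nucleotide phosphodiesterase, was higher by 3.12 ± 0.40, with 40.2 to 52.7 CPM in the posterior fossa tumours and 2.92 to 8.18 CPM in the supratentorial ones. KDM7A-DT, a divergent transcript at the KDM7A gene, was higher by 2.94 ± 0.40, and its reads cannot be told from those of an overlapping gene.

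Among the genes lower in posterior fossa tumours, HES3 had a log2 fold change of -10.77 ± 0.76 (edgeR adjusted p = 0.00462), FBP2 of -9.29 ± 1.05 (edgeR adjusted p = 0.0208) and NR2E1 of -9.51 ± 0.92 (edgeR adjusted p = 0.0135). MUC2, a secreted mucin, had a log2 fold change of -10.11 ± 1.08 and CCDC187 of -9.9 ± 1.01, with 12.2 to 178 and 33.4 to 329 CPM in the supratentorial tumours. ESX1, a homeobox gene, had -9.69 ± 0.80, and ECEL1, a neuronal endopeptidase, -9.0 ± 1.33. CHD5, a chromatin remodeller of neurons, had -9.42 ± 1.45, at 2.91 ± 4.22 CPM (SD, n = 5) with 10.4 CPM in PF13, against 449, 562 and 5000 CPM in ST1, ST2 and ST3. TBXT, the notochord transcription factor, had 3 counts in the 5 posterior fossa tumours together and a ratio between the groups of 1070 (95% counting interval 366 to 5190). In GENCODE 29 on GRCh38, HES3 lies on chromosome 1 from 6244192 to 6245578 and CHD5 on chromosome 1 from 6101793 to 6180123. IRX1 lies on chromosome 5 from 3596054 to 3601403 and AQP1 on chromosome 7 from 30911694 to 30925516.

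Without PF14, a comparison adopted after the data were seen, 321 of 30917 genes were higher and 337 lower, and these included every one of the 12 and 105 genes called with 8 tumours, in the same direction. Leaving out PF1, PF3, PF4 or PF13 left 0, 0, 0 and 3 genes higher and 5, 3, 7 and 34 lower, and leaving out ST1, ST2 or ST3 left 1, 0 and 0 higher and 30, 23 and 17 lower. DESeq2 called 865 genes higher and 746 lower with 8 tumours. Of the genes named above, HES3 was called by edgeR whichever of the 8 tumours was left out, while IRX1 and AQP1 kept their calls only without PF14. Genes with the largest folds without PF14 included PAX3, a transcription factor of the dorsal neural tube, at 9.48 ± 1.48 (edgeR adjusted p = 0.0265), and RELN, a secreted guide of neuron migration, at 6.90 ± 0.70 (edgeR adjusted p = 0.00926). LGR6, a receptor for R-spondins, was at 7.50 ± 1.24, DAO, D-amino acid oxidase, at 7.98 ± 1.51 and SEMA3D, a secreted semaphorin, at 6.97 ± 1.20. With all 8 tumours these 5 genes did not pass, with edgeR adjusted p from 0.16 to 0.241; in PF14 PAX3 was at 0.124 CPM and RELN at 6.57 CPM.

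**Figure D2:**
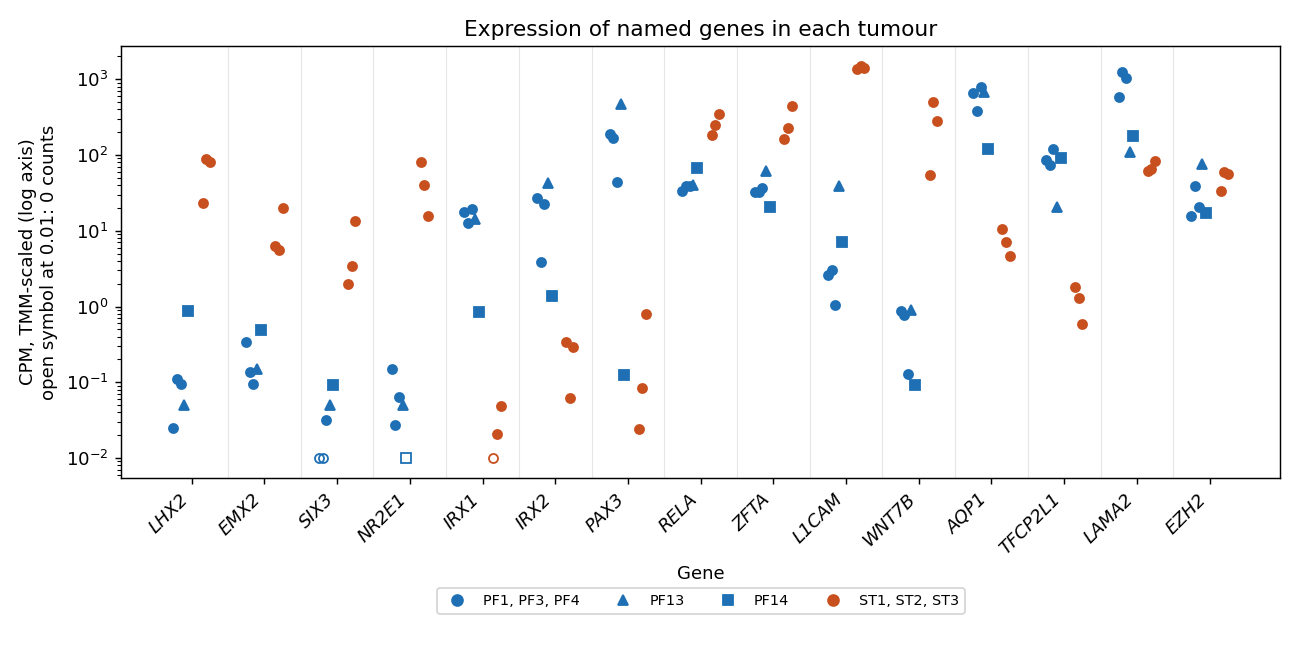
Expression of 15 named genes in each tumour, 1 symbol per tumour, with CPM on a log axis and open symbols at 0.01 where a tumour had 0 counts. LHX2 and L1CAM are higher in each supratentorial tumour than in any posterior fossa tumour, and AQP1 and TFCP2L1 are lower; the 3 L1CAM values of the supratentorial tumours lie between 1350 and 1500 CPM.

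Transcription factors of the developing forebrain were lower in posterior fossa tumours. The log2 fold changes of LHX2, SIX3 and EMX2 were -8.13 ± 1.17, -7.41 ± 1.08 and -5.41 ± 0.72 (SE; edgeR adjusted p = 0.039, 0.0412 and 0.0296). Of 28 members 17 were expressed enough to be tested, NR2E1 among them. Of these, 5 were lower and 0 higher over all genes, and 7 lower and 1 higher adjusted over the list alone. The list scores of PF1, PF3 and PF4 were only -2.03 to -1.86, so members could be kept for testing through supratentorial tumours alone. That favours a negative sign, and the list results that follow are not free of it. The median member was at -3.69 (camera adjusted p = 2.9e-12; adjusted p = 0.05 with an estimated correlation), and the mean score was -1.42 ± 0.71 (SD, n = 5) against 2.01 ± 1.09 (SD, n = 3), with an exact permutation p = 0.0357 and an adjusted p = 0.378 over 37 lists. Without PF14, 5 members were lower and 1 was higher. Only the comparison without PF14 kept the calls of LHX2, SIX3 and EMX2 among those that left out 1 tumour.

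Hindbrain transcription factors did not move together. IRX1 was the 1 of 24 tested members called, with 3 higher and 2 lower adjusted over the list alone (camera adjusted p = 0.25). IRX2 and PAX3 had log2 fold changes of 6.38 ± 1.38 and 9.17 ± 2.48 (SE; edgeR adjusted p = 0.135 and 0.223), and LMX1B, a factor of the isthmus, of -7.27 ± 1.30 (edgeR adjusted p = 0.0745). PF14 had the lowest hindbrain score of the 8 tumours, -0.21, with IRX1 at 0.836 CPM. Without PF14, IRX1, IRX2 and PAX3 were higher and LMX1B was lower, 6 were higher and 2 lower adjusted over the list alone, and the list was called (camera adjusted p = 0.0071; adjusted p = 0.45 with an estimated correlation).

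Of 15 anterior HOX genes, which pattern the hindbrain, 7 were expressed enough to be tested. All 7 had positive fold changes, with a median of 5.54. None passed over all genes and 6 were higher adjusted over the list alone (camera adjusted p = 4.8e-05, or 0.48 with an estimated correlation). Their scores in the supratentorial tumours were only -2.91 to -2.39, so members could be kept for testing through posterior fossa tumours alone. That favours a positive sign, and neither the shared sign nor the camera result is free of it. Without PF14 only 3 members were expressed enough to be tested, all 3 higher adjusted over the list alone (camera adjusted p = 0.0024; adjusted p = 0.47 with an estimated correlation), and without PF13 and PF14 only 2, fewer than the 3 needed for camera. HOXB3 was at 37.8 CPM in PF3, 31.6 in PF4, 15 in PF13 and 3.31 in PF14, but at 0.246 CPM in PF1, below the 0.272 to 0.481 CPM of the supratentorial tumours (edgeR adjusted p = 0.227). HOXB4 was at 11.3 CPM in PF3 and 0.05 CPM in PF13. Of the posterior HOX genes only 2 of 24 were expressed enough to be tested, with no call over all genes or adjusted over the list alone; both were highest in PF14, and without PF14 none was tested.

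Known markers of supratentorial ependymomas that carry a RELA fusion were lower in posterior fossa tumours. Whether these tumours carry such a fusion was not tested, and CLDN1 belongs both to this list and to that of posterior fossa group A. ELL3, an elongation factor, had a log2 fold change of -5.0 ± 0.53, ZFTA, a zinc finger gene, of -2.91 ± 0.44 and RELA, an NF-kB subunit, of -2.58 ± 0.33 (SE; edgeR adjusted p = 0.0159, 0.0423 and 0.0264). L1CAM, a cell adhesion protein, was at 10.6 ± 16.1 CPM (SD, n = 5) against 1420 ± 74.1 CPM (SD, n = 3), a log2 fold change of -7.06 ± 1.21 that did not pass (edgeR adjusted p = 0.0625), with 39.2 CPM in PF13. CCND1, cyclin D1, was at 174 ± 136 against 631 ± 174 CPM (edgeR adjusted p = 0.402). In all, 3 of 16 tested members were lower, and 9 adjusted over the list alone (camera adjusted p = 3.2e-14; adjusted p = 0.11 with an estimated correlation). The score was 3.62 ± 0.69 against 5.85 ± 0.60, with an exact permutation p = 0.0357 and an adjusted p = 0.378. Without PF14 L1CAM and JAG1, a Notch ligand, were also lower (edgeR adjusted p = 0.0437 and 0.039), while the calls of RELA and ZFTA were lost when any of the other 7 tumours was left out.

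No marker of group A posterior fossa ependymoma passed over all genes or adjusted over the list alone, although 12 of 14 had positive fold changes. LAMA2, a laminin, was at 629 ± 504 against 69.6 ± 11.3 CPM (edgeR adjusted p = 0.227), with 110 CPM in PF13 and 176 CPM in PF14. TNC, tenascin C, ran from 228 to 3740 CPM in posterior fossa tumours and from 110 to 803 CPM in supratentorial ones (edgeR adjusted p = 0.591). The median log2 fold change was 1.82 (camera adjusted p = 0.019; adjusted p = 0.68 with an estimated correlation). Without PF14 3 were higher adjusted over the list alone, and without PF13 and PF14 2 were higher over all genes. PF13 and PF14, left out after the data were seen, had the lowest scores of this list in their group. The camera call was lost without PF3, PF4 or ST1 (camera adjusted p = 0.07, 0.05 and 0.14) and with limma voom (adjusted p = 0.067).

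Genes of PRC2, the complex that writes H3K27me3, gave no call over all genes. EZH2, the catalytic subunit, was at 33.9 ± 25.6 against 49.6 ± 14.4 CPM, SUZ12 at 46.5 ± 5.06 against 75.3 ± 21.8 CPM, and EED at 28.6 ± 5.37 against 26.2 ± 2.38 CPM (edgeR adjusted p = 0.775, 0.403 and 0.901). EZHIP, an inhibitor of PRC2, was at 3.36 ± 2.15 against 1.07 ± 0.793 CPM, a log2 fold change of 1.64 ± 1.05 (edgeR adjusted p = 0.637), with 2.29 to 5.49 CPM in PF1, PF3, PF4 and PF13 and 0.124 CPM in PF14. The H3K27 demethylases KDM6A and KDM6B had log2 fold changes of 0.08 ± 0.32 and -0.23 ± 0.36 (edgeR adjusted p = 0.953 and 0.867). The signs for EED and KDM6A turned with library size alone. Of 16 members none was called and 1 was higher adjusted over the list alone (camera adjusted p = 0.92); the median was -0.14 and the mean 0.14. That 1 was EPOP, a PRC2 accessory protein, at 6.01 to 18 CPM against 0.529 to 2 CPM, with a log2 fold change of 3.04 ± 0.60 (edgeR adjusted p = 0.0981); it was higher over all genes without PF14 (3.19 ± 0.56, edgeR adjusted p = 0.0364). Taken in either direction by fry, the list passed (mixed adjusted p = 0.0013, and 0.00012 without PF14); with all 8 tumours 10 of the 37 lists passed in this way.

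Subunits of Polycomb repressive complex 1 and the DNA methylation enzymes gave no call over all genes. Of 19 tested PRC1 genes, 1 was lower adjusted over the list alone (camera adjusted p = 0.43). Without PF14, 1 was lower and 1 higher over all genes, the latter BMI1, with a log2 fold change of 1.67 ± 0.28 (edgeR adjusted p = 0.0327); BMI1 was at 16.8 CPM in PF14. Of 17 tested DNA methylation genes none passed over all genes or adjusted over the list alone (camera adjusted p = 0.92). DNMT1, the maintenance methyltransferase, was at 78.4 ± 42.0 against 80.7 ± 24.9 CPM, DNMT3A at 136 ± 83.4 against 211 ± 102 CPM and DNMT3B at 4.81 ± 1.97 against 3.54 ± 1.21 CPM (edgeR adjusted p = 0.984, 0.714 and 0.787).

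Developmental regulators of non-neural lineages, which Polycomb represses in embryonic stem cells, were lower on balance in the posterior fossa tumours, with a median of -0.68 (camera adjusted p = 0.0037; adjusted p = 0.48 with an estimated correlation). TBXT was the 1 of 29 tested members called, also adjusted over the list alone, with a log2 fold change of -9.84 ± 1.20 (SE; edgeR adjusted p = 0.0231), and 8 members had positive fold changes. Of 59 members only these 29 were expressed enough to be tested, and members could be kept through supratentorial tumours alone. That favours a negative sign, and the median, the camera result and the score are not free of it. The score was 0.25 ± 0.32 against 1.21 ± 0.46 (exact permutation p = 0.0357, adjusted p = 0.378). TBX5, a T-box factor of heart and forelimb, was at 0.693 ± 1.40 against 36.1 ± 29.1 CPM (edgeR adjusted p = 0.293), with 3.19 CPM in PF14. Without PF14 the median was -1.05 and TBX5 and TBX15 were lower too, with log2 fold changes of -8.92 ± 1.21 and -2.97 ± 0.52 (edgeR adjusted p = 0.0184 and 0.0352).

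Cyclin-dependent kinase inhibitors had negative fold changes in all 7 tested members, with a median of -1.14 (camera adjusted p = 0.0056; adjusted p = 0.48 with an estimated correlation; camera adjusted p = 0.075 without ST3). None passed over all genes and 1 was lower adjusted over the list alone, or 3 without PF14. CDKN1B, p27, was at 46.0 ± 2.37 against 81.2 ± 17.2 CPM (edgeR adjusted p = 0.244). CDKN2A was at 1.05 ± 1.28 against 8.02 ± 7.05 CPM (edgeR adjusted p = 0.401), with 3.31 CPM in PF14 and 0.355 CPM in ST2.

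Motile cilium genes, the apparatus of ependymal cells, had positive fold changes in 48 of 50 tested members, with a median of 1.51, but none passed over all genes or adjusted over the list alone. The cilia score was 7.01, 5.40 and 7.66 in PF1, PF3 and PF4, 4.22 in PF13, -0.13 in PF14, and 3.77 to 5.19 in the supratentorial tumours. The list was called (camera adjusted p = 0.012; adjusted p = 0.83 with an estimated correlation), but not without PF1, PF4 or ST3 (camera adjusted p = 0.27, 0.74 and 0.1) or with limma voom (adjusted p = 0.26). Without PF14 1 member was higher over all genes (camera adjusted p = 3e-10, or 0.77 with an estimated correlation of 0.86). Without PF13 and PF14 6 of 50 were higher over all genes and 37 adjusted over the list alone (camera adjusted p = 2e-19). PF13 and PF14 had the lowest cilia scores of their group and were left out after the data were seen. Their removal therefore raised the group by construction. No correlation was estimated for that fit, and the preset of 0.01 is far below 0.86. ODAD1, a dynein docking protein, was at 0.434 CPM in PF14 and higher without it, with a log2 fold change of 5.39 ± 0.99 (edgeR adjusted p = 0.0401).

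Astrocyte genes varied widely within the posterior fossa group. GFAP was at 8010 ± 8130 against 955 ± 317 CPM (edgeR adjusted p = 0.583), and the astrocyte score was 2.36 in PF14 and at least 5.76 in the other 7 tumours. None of 20 tested members was called and 1 was lower adjusted over the list alone (camera adjusted p = 0.18). Without PF14, S100B and NDRG2 were higher by 3.86 ± 0.70 and 3.78 ± 0.74 (edgeR adjusted p = 0.0383 and 0.0455), 7 members were higher adjusted over the list alone, and the list was called (camera adjusted p = 0.00062; adjusted p = 0.77 with an estimated correlation). Radial glia genes gave no call in 24 tested members, over all genes or adjusted over the list alone (camera adjusted p = 0.69), and their median and mean of 0.23 and 0.10 were positive while camera placed the list lower. The radial glia score was 3.17 in PF14 and at least 5.63 elsewhere; without PF14 ID4, a helix-loop-helix inhibitor, was higher by 2.10 ± 0.40 (edgeR adjusted p = 0.043).

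Choroid plexus genes were led by AQP1, the 1 of 19 tested members called, also adjusted over the list alone (camera adjusted p = 0.1, and 0.045 without PF13). Oligodendrocyte precursor genes gave no call in 14 tested members and 1 higher and 1 lower adjusted over the list alone, or 4 and 1 without PF14 (camera adjusted p = 0.72 with all 8 tumours). VCAN and BCAN, matrix proteoglycans, were at 1050 ± 699 against 149 ± 87.4 CPM and at 367 ± 330 against 54.8 ± 29.3 CPM (edgeR adjusted p = 0.178 and 0.579), with BCAN at 0.62 CPM in PF14. Myelin genes of oligodendrocytes had a median log2 fold change of -1.34 in 18 tested members, with no call over all genes or adjusted over the list alone (camera adjusted p = 0.00012; adjusted p = 0.68 with an estimated correlation). Their score was 0.66 in PF14, 1.24 to 3.31 in the other posterior fossa tumours and 2.24 to 4.43 in the supratentorial ones.

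Neuronal genes were lower on balance in posterior fossa tumours, with positive fold changes in only 3 of 24 tested members and a median of -0.96 (camera adjusted p = 5.4e-06; adjusted p = 0.71 with an estimated correlation). None passed over all genes or adjusted over the list alone. The neuron score was 4.20 in PF13, -1.19 to 0.72 in the other posterior fossa tumours and 1.78 to 4.12 in the supratentorial ones; without PF13 the median was -2.65 and 14 members were lower adjusted over the list alone, and without PF13 and PF14 3 were lower over all genes. PF13 had the highest neuron score of its group, so leaving it out lowered the group by construction. Cerebellar neuron genes had a median of 1.56 in 17 tested members, with no call over all genes and 2 higher adjusted over the list alone (camera adjusted p = 0.027; adjusted p = 0.71 with an estimated correlation). The call was lost without PF13, ST1, ST2 or ST3 (camera adjusted p = 0.8, 0.12, 0.053 and 0.067) and with limma voom (adjusted p = 0.11). RELN, a member of this list, was at 647 to 1380 CPM in PF1, PF3, PF4 and PF13, at 6.57 CPM in PF14 and at 2.82 to 12.4 CPM in the supratentorial tumours.

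**Figure D3:**
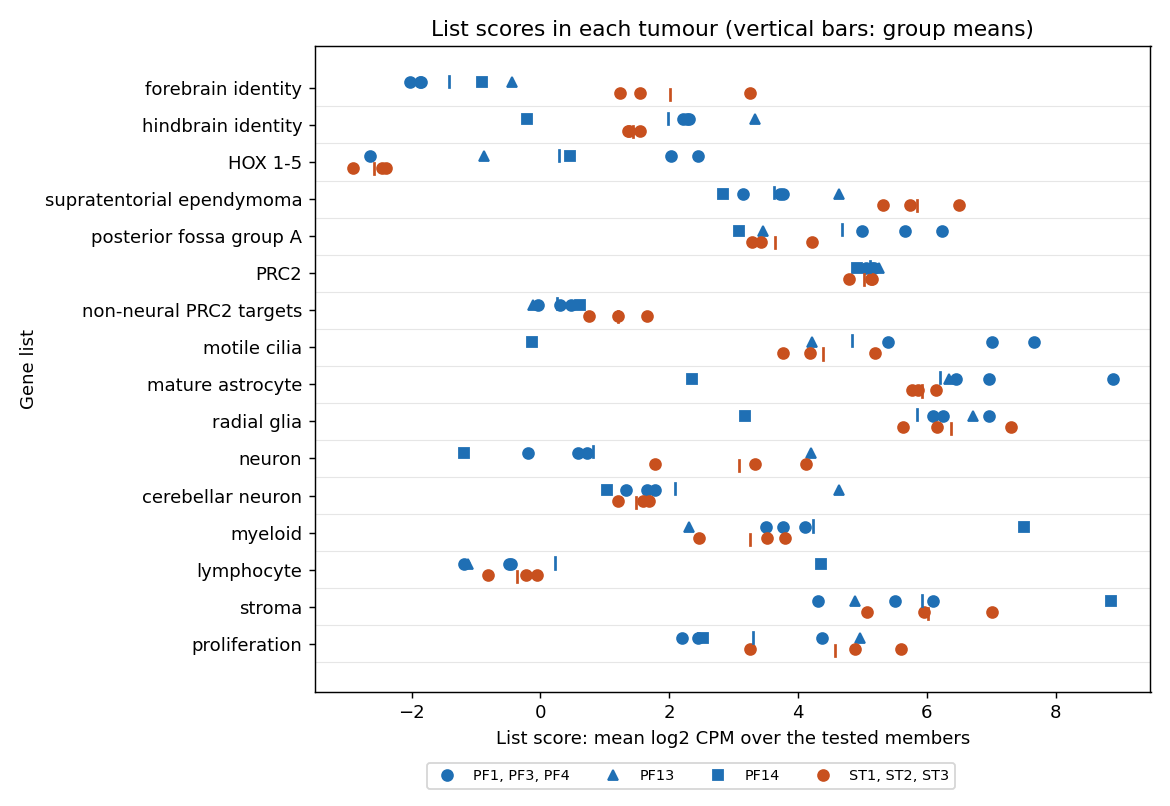
Scores of 16 gene lists in each tumour, the mean log2 CPM of the tested members, with vertical bars at the group means. The forebrain identity and supratentorial ependymoma scores do not overlap between the groups, PF14 has the highest myeloid, lymphocyte and stroma scores at 7.50, 4.35 and 8.85, and PF13 has the highest cerebellar neuron score at 4.63.

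Genes of microglia and macrophages had positive fold changes in 23 of 23 tested members, with a median of 2.57 (camera adjusted p = 0.0039; adjusted p = 0.81 with an estimated correlation), and 21 of the 23 were highest in PF14. Without PF14 the median was 0.18 (camera adjusted p = 0.58), and without ST3 the camera adjusted p was 0.066. Lymphocyte genes had a median of 2.91 in 20 tested members, 19 of them highest in PF14 (camera adjusted p = 0.066, or 0.83 with an estimated correlation). At the preset correlation the list was called higher without PF1, PF3, PF4, PF13 or ST2 (camera adjusted p = 0.0044, 0.019, 0.019, 0.013 and 0.046). It was also called with library size alone (camera adjusted p = 0.015) and with no filter (0.033). Without PF14 the median was -0.44 in the 16 members then tested (camera adjusted p = 0.17). Stroma genes had a median of 0.91 and a mean of 1.09 in 19 tested members, while camera placed the list lower (camera adjusted p = 0.75). In PF14 15 of the 19 were highest, and without it the median was -1.0 (camera adjusted p = 0.0071; adjusted p = 0.82 with an estimated correlation). Endothelial genes had a median of -0.31 in 20 tested members (camera adjusted p = 0.025; adjusted p = 0.71 with an estimated correlation), a call lost without PF13, ST2 or ST3 (camera adjusted p = 0.19, 0.066 and 0.075); without PF14 the median was -0.70, with 0 of 20 positive (camera adjusted p = 0.0026; adjusted p = 0.61 with an estimated correlation). Erythroid genes had a median of 1.01 in 7 tested members (camera adjusted p = 0.33). None of these 5 lists had a member called over all genes or adjusted over the list alone.

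WNT7B and WNT3A, secreted WNT ligands, were lower in posterior fossa tumours by log2 fold changes of -8.95 ± 1.06 and -7.98 ± 1.20 (SE; edgeR adjusted p = 0.022 and 0.0423). Of 31 tested WNT genes these 2 were called, and 1 was higher and 6 lower adjusted over the list alone (camera adjusted p = 0.062); the median was 0.06, the mean -0.48, and camera placed the list lower. It was called lower without PF4, PF13, ST1 or ST2 (camera adjusted p = 0.021, 0.043, 0.036 and 0.0033), and the median without PF14 was 0.20. Without PF14 SP5, a WNT-induced factor, was lower and RSPO2, an R-spondin, was higher, with log2 fold changes of -3.74 ± 0.67 and 5.90 ± 0.90 (edgeR adjusted p = 0.0379 and 0.0249); RSPO2 was at 0.031 CPM in PF14. Notch pathway genes had a median of -0.41 in 24 tested members, with no call over all genes and 1 higher and 6 lower adjusted over the list alone (camera adjusted p = 0.0031; adjusted p = 0.5 with an estimated correlation). NOTCH1 was at 257 ± 72.6 against 859 ± 619 CPM (edgeR adjusted p = 0.269). The ligands JAG1 and JAG2 had log2 fold changes of -2.45 ± 0.43 and -4.28 ± 0.84 (edgeR adjusted p = 0.0708 and 0.0973), and both were lower without PF14 (edgeR adjusted p = 0.039 and 0.0482).

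Hedgehog genes gave no call in 16 tested members and 1 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.4, and 0.023 without PF13). Hippo-YAP genes gave none in 20, with 1 lower adjusted over the list alone (camera adjusted p = 0.23); the median of 0.10 and the mean of -0.13 differed in sign, and camera placed the list lower. Without PF14 the medians of the Hedgehog and Hippo-YAP lists were -0.16 and -0.35, against -0.36 and 0.10 with it. RELA was the 1 of 27 NF-kB genes called, also adjusted over the list alone, and it was lower, while 23 members had positive fold changes with a median of 1.53 (camera adjusted p = 0.14). The NF-kB score was 6.03 in PF14 and at most 4.24 elsewhere, and without PF14 the median was 0.12; the list was called higher without PF1, PF13 or ST2 (camera adjusted p = 0.0082, 0.0047 and 0.038). Receptor tyrosine kinases gave no call in 32 tested members and 1 higher and 5 lower adjusted over the list alone, or 5 and 6 without PF14 (camera adjusted p = 0.15 with all 8 tumours, and 0.045 without ST1). Without PF14 NTRK2, NTRK3 and EPHA7 were higher by 3.11 ± 0.62, 1.86 ± 0.37 and 3.35 ± 0.56 (edgeR adjusted p = 0.0482, 0.0463 and 0.0307), and MERTK, a phagocytic receptor, was lower with a log2 fold change of -2.85 ± 0.33 (edgeR adjusted p = 0.0127). NTRK2 was at 15.1 CPM in PF14 and at 1690 CPM or more in the other posterior fossa tumours.

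Collagen and matrix genes went both ways, with no call in 40 tested members and 3 higher and 3 lower adjusted over the list alone, or 6 and 4 without PF14 (camera adjusted p = 0.75 with all 8 tumours). Without PF14 COL9A3 and COL18A1 were lower and LAMA1 and ECM2 were higher, with log2 fold changes of -6.54 ± 1.21, -3.55 ± 0.56, 2.0 ± 0.37 and 4.21 ± 0.82 (edgeR adjusted p = 0.0403, 0.0271, 0.0401 and 0.0458). The matrix median was 0.53 with PF14 and -0.54 without it.

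Mitotic cell cycle genes had negative fold changes in 31 of 31 tested members, with a median of -1.10, and none passed over all genes or adjusted over the list alone (camera adjusted p = 3.3e-07; adjusted p = 0.71 with an estimated correlation). The proliferation score was 2.20 to 2.52 in PF1, PF4 and PF14, 4.37 in PF3 and 4.96 in PF13, against 3.26 to 5.59 in the supratentorial tumours (exact permutation p = 0.214, adjusted p = 0.566). Replication-dependent histone genes had a median of -0.96 in 60 tested members (camera adjusted p = 1.8e-05; adjusted p = 0.81 with an estimated correlation; camera adjusted p = 0.44 without ST2). Ribosomal protein genes had a median of 0.28 in 78 (camera adjusted p = 0.019; adjusted p = 0.83 with an estimated correlation), a call lost with library size alone and without PF13, PF14 or ST1 (camera adjusted p = 0.081, 0.18, 0.35 and 0.48). Hypoxia and glycolysis, interferon, immediate early and mitochondrial genes had medians of 0.19, 1.01, -0.19 and 0.21 in 30, 28, 21 and 13 tested members (camera adjusted p = 0.4, 0.085, 0.14 and 0.48), and of 0.12, 0.47, -0.49 and 0.15 without PF14 (camera adjusted p = 0.53, 0.87, 0.04 and 0.65). The interferon list was called higher without PF1, PF3, PF13 or ST2 (camera adjusted p = 0.0059, 0.013, 0.0032 and 0.0018) and with library size alone (0.049). The immediate early list was called lower without PF4 or ST2 (camera adjusted p = 0.0044 and 0.037) and with limma voom (0.046), but not without PF14 with an estimated correlation (adjusted p = 0.9), and the hypoxia list higher without ST2 (camera adjusted p = 0.00099). Without PF14 the ribosomal median was 0.16. With all 8 tumours none of these 6 lists had a member called over all genes or adjusted over the list alone. Without PF14, 1 immediate early gene was lower adjusted over the list alone.

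Of the 37 lists tested, camera called 16 at its preset correlation, 6 higher and 10 lower in posterior fossa tumours. With an estimated correlation it called 0 (smallest adjusted p = 0.05), and limma's fry called 2, forebrain identity and supratentorial ependymoma (adjusted p = 0.02 and 0.027). Without PF14 camera called 18, and 0 with an estimated correlation. The fit with the tumour number as a block rests on PF1 against ST1 and PF3 against ST3 alone. In that fit camera no longer called the cerebellar neuron, oligodendrocyte and ribosomal lists (camera adjusted p = 0.6, 0.24 and 0.65). Of the lists that camera did not call in the main comparison of all 8 tumours it called 8, some of them also called with a tumour left out, as given above. These were mature astrocyte, oligodendrocyte precursor, choroid plexus, hypoxia and radial glia, higher, and stroma, WNT and immediate early, lower. Of the list scores, 3 reached the smallest exact permutation p of 0.0357, and none passed after adjustment over the lists.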

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

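The tests of depth, swapped labels and a single share for PF14, and of a wrong group and admixed tissue for PF13, were chosen after the results were seen, and the weight given to AQP1 and TFCP2L1 in the test of another tissue was set then too. Within the posterior fossa group, the gap between the highest or lowest tumour and the nearest other was compared with the range of the group for 44 scores and measures and 73 genes, and 20 stood apart, 14 of them in PF14, 3 in PF13, 2 in PF4 and 1 in PF3. Chance alone sets about 1 in 20 such values apart, but this is no test for PF14: of its 14, 6 were among 25 genes picked only from the comparison without PF14, which favours genes where it differs, 6 among the 48 other genes and 2 among the scores. The supratentorial group of 3 was too small to be tested.

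PF14 had the highest or lowest value of the group by a wide gap in many genes. Its scores were 3.17 for radial glia, against 6.10 or more in the other posterior fossa tumours, and 4.35 for lymphocytes, against -0.45 or less. Its log2 CPM was -0.17 for IRX1, 2.73 for RELN, -2.51 for EZHIP, 4.07 for BMI1, 0.22 for S100B, 2.52 for ID4 and -0.58 for BCAN, each below the other posterior fossa tumours. It was also lower in RSPO2 (-3.60), NTRK2 (3.93), EPHA7 (-1.47) and LAMA1 (3.75), and higher in RELA (6.08). COL1A1, a fibroblast collagen, had 476859 counts in PF14 and CD74, an antigen presentation gene of myeloid cells, 256399, against 181 for GFAP and 67 for AQP4, an astrocyte water channel.

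Tables argue against a shallow library or a high mitochondrial share for PF14, since 0 of 3 measures (total count, mitochondrial ribosomal RNA, nuclear coding share) lay outside the range of the other 7 libraries, although its 39917 detected genes and its 1.69% of small noncoding RNA were below theirs. They also argue against labels swapped between the groups, since each supratentorial tumour correlated better with the others of its group than with PF1, PF3, PF4 or PF13, by at least 0.023. Dilution of ordinary tumour cells to a single share could not be excluded: GFAP, AQP4 and the median cilia gene stood at 0.0602%, 0.102% and 0.664% of the median of the other posterior fossa tumours, 11-fold apart, and the median astrocyte and radial glia genes at 2.29% and 12.2%, a spread that goes against a single share unless other cells express the higher ones, which was not measured. A sample of another tissue could not be excluded. In PF14 the median of the genes higher in the other posterior fossa tumours lay -0.50 on the log2 scale from the highest supratentorial tumour. IRX1, AQP1 and TFCP2L1 were at 0.836, 120 and 90.6 CPM in PF14 and at most 0.0486, 10.6 and 1.8 CPM in supratentorial tumours. The rule that picked them required every posterior fossa tumour, PF14 included, to lie above every supratentorial one. Their levels in PF14 therefore cannot decide whether the sample is of another tissue. A tumour with few ependymal and many stromal and immune transcripts is a biological difference that was not tested. Of the 337 genes lower in posterior fossa tumours without PF14, 278 were lower in PF14 too than in all 3 supratentorial tumours. These genes were called for high levels in the same supratentorial tumours, which favours lower levels in any sample unlike them. The 278 therefore cannot tell such a tumour from another tissue. Of the 321 genes higher only 112 were above all 3 in PF14 and 138 were below all 3.

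PF13 stood apart in neuronal transcripts, with a cerebellar neuron score of 4.63 against 1.78 or less, a log2 CPM of 3.39 for CHD5 against 0.63 or less, and 4.38 for TFCP2L1 against 6.2 or more. A tumour of the supratentorial group under a wrong label is argued against but not excluded. Of the 37 genes called without PF13, a choice that did not use its level, 29 were also called with PF13 counted as a posterior fossa tumour. HES3, called without PF13 (edgeR adjusted p = 0.0189), was at 0.025 CPM in PF13 and at 20.3 CPM or more in the supratentorial tumours. LHX2, EMX2, SIX3 and NR2E1 were at least 26.6-fold lower in PF13 than in the lowest supratentorial tumour. They were picked at the end from calls that count PF13 as a posterior fossa tumour, which favours low levels there. Rank correlations of PF13 were 0.89, 0.903 and 0.859 with PF1, PF3 and PF4, and 0.874, 0.896 and 0.877 with ST1, ST2 and ST3. The forebrain score, from a list fixed beforehand, was -0.44 in PF13. This lay between the -2.03 to -1.86 of PF1, PF3 and PF4 and the 1.23 to 3.25 of the supratentorial tumours. The hindbrain score, also from a list fixed beforehand, was 3.33 in PF13. It was 2.22 to 2.30 in PF1, PF3 and PF4 and 1.36 to 1.54 in the supratentorial tumours. Admixed cerebellar tissue stays open: GABRA6, CBLN3 and FAT2, genes of granule neurons, were at 20.6, 35.5 and 428 CPM, at least 20.1-fold above the highest of PF1, PF3 and PF4, but they belong to the list whose score prompted the test, so they restate the pattern and do not support this explanation. Of the cerebellar list 9 of 17 members reached 1 CPM in PF1, PF3 and PF4 too, 2 are in another list, and 12 were higher in PF13 than in those tumours. A tumour that expresses these genes itself stays open too and was not tested.

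Library measures set 2 tumours apart. Mitochondrial ribosomal RNA took 24.95% of counts in PF4, against 11.79% to 13.63% in the other posterior fossa tumours, and nuclear protein-coding genes took 66.91% there against 75.43% or more. Other mitochondrial transcripts took 0.58% in PF3 against 0.83% or more.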

How the results depend on the processing

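Comparisons without PF14, except its leave-one-out count, those without PF13 and PF14, and the splits of the list tests were chosen after the results were seen. With all 8 tumours the counts of genes higher and lower (12 and 105 in edgeR) became 6 and 109 with library size alone, 865 and 746 with DESeq2, 160 and 321 with limma voom and quality weights, 0 and 2 at an adjusted p under 0.01, and 776 and 470 without PF13 and PF14. Leaving out 1 tumour gave 0 to 321 higher and 3 to 337 lower, moving by over 1.5 times for each tumour. The other scalings, filters and tools gave 9 to 16 higher and 82 to 121 lower. Without PF14 (321 and 337) the counts became 2010 and 1289 with DESeq2, 203 higher with limma voom, and 11 and 18 at an adjusted p under 0.01. With the tumour number as a block, 0 genes were called in either direction by edgeR. In that fit 4300 genes had an unadjusted p under 0.05, and the smallest edgeR adjusted p was 0.0949. Only numbers 1 and 3 are shared between the groups, so this fit compares PF1 with ST1 and PF3 with ST3 alone. The deviations of these numbers correlated at 0.193 and -0.027, so the numbers were not taken to pair the tumours. The cause of these moves was not tested, except that fewer tumours, in the block fit too, and a stricter threshold act by construction.

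The gene counts argue against chance but cannot exclude it, since the real split ranking first is the strongest outcome these splits allow. Of 56 splits of 8 tumours only 1, the real one, called as many genes as the 12 plus 105 found (highest other 41). Of 35 splits of the 7 without PF14 only 1, the real one, called as many as 658 (highest other 138). PF14 had been left out after the data were seen. The highest others in both cases set PF1, PF3 and PF4 apart from the rest. For the number of lists, chance is not argued against: 28 of 56 splits called as many as 16 (highest other 24). Without PF14, 12 of 35 called as many as 18 (highest other 21). Lists called became 0 with an estimated correlation, 2 with fry and 0 without PF14 with an estimated correlation; the others gave 11 to 21. For the similarity of the libraries, the first principal component held 42.4% over all tested genes. No list score passed adjustment in any setting.

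Of 93 genes that the text names, 34 were called; these kept their direction in all 544 alternatives and their call in 300, with 95 of 102 scaling alternatives and 87 of 272 that left out 1 tumour. Direction turned in 17 of 1482 alternatives, in 7 genes that were not called: the log2 fold change of COL1A1 (-0.11, -1.13 and -2.41) with voom, voom quality weights and the block, EED (-0.04) and KDM6A (-0.13) with library size alone, KDM6A (-0.04) with voom quality weights, and CBLN3 (-0.07) and FAT2 (-0.09) with the block. Leaving out 1 tumour gave -0.36 (without PF14) to 3.78 for COL1A1, -0.07 to 0.20 for KDM6A, -0.48 to 0.07 for KDM6B and -0.39 to 0.14 for DNMT1, and the cause was not tested. Of 51 further genes that the rule picked and the text does not name, none was called with all 8 tumours; direction turned for 28 of them, in 82 of 807 alternatives, and for 8 without PF14. Depth limits genes at a few counts, such as HES3 and IRX1 in the lower group, where the fitted fold change depends on the prior count and the ratio has a wide counting interval, and 6 alternatives gave no value: HOXB4 was filtered out without PF3, PF4 or PF14, and DESeq2 gave no adjusted p for FAT2, JAG2 and CD74.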

Other observations

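The genes of the first 2 paragraphs were chosen after their values were seen, and the tests of neighbouring genes on the calls without PF14 were added after the test on all 8 tumours was seen. FLG, FLG2, ITGB4 and DMKN, single genes expressed in epidermis, were higher in posterior fossa tumours without PF14, and no list of such genes was tested. FLG and FLG2, filaggrins of the cornified layer, were at 84.0 ± 58.1 and 10.9 ± 8.44 CPM (SD, n = 4) against 3.68 ± 1.11 and 0.529 ± 0.204 CPM (SD, n = 3), log2 fold changes of 4.52 ± 0.60 and 4.36 ± 0.74 (SE; edgeR adjusted p = 0.0182 and 0.0317). ITGB4, an integrin of hemidesmosomes, was higher by 5.45 ± 0.84 (edgeR adjusted p = 0.0263), and DMKN, a secreted protein of epidermis, by 5.60 ± 0.60 (edgeR adjusted p = 0.011). With PF14, only DMKN of these 4 passed (edgeR adjusted p = 0.0497), and FLG, FLG2 and ITGB4 stood at 0.096, 0.143 and 0.16.

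CRH and CCK, each the gene of a neuropeptide, were lower in posterior fossa tumours, and no list of neuropeptide genes was tested. CRH, corticotropin-releasing hormone, and CCK, cholecystokinin, had log2 fold changes of -6.88 ± 0.66 and -5.58 ± 0.88 (SE; edgeR adjusted p = 0.0133 and 0.0462), at 0.0268 ± 0.0179 and 0.0216 ± 0.0359 CPM (SD, n = 5) against 3.60 ± 1.58 and 1.20 ± 0.25 CPM (SD, n = 3). NPY, neuropeptide Y, and PNOC, the nociceptin precursor, had -5.63 ± 1.03 and -4.79 ± 1.12 (edgeR adjusted p = 0.0812 and 0.161), and both were lower without PF14 (edgeR adjusted p = 0.0379 and 0.0266). PCP4L1, a calmodulin-binding protein, had the smallest edgeR adjusted p of all genes, 0.00444, at 0.979 ± 0.378 against 174 ± 64.1 CPM, and it was called whichever of the 8 tumours was left out.

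Some genes lower in posterior fossa tumours lay near each other. On chromosome 1 CHD5, HES3 and ACOT7, an acyl-CoA thioesterase, lie between 6101793 and 6394391 (GENCODE 29, GRCh38) and had log2 fold changes of -9.42, -10.77 and -2.62 (edgeR adjusted p = 0.0429, 0.00462 and 0.0296). GPR153, an orphan receptor of chromosome 1, was at 40.5 CPM in PF14 and 2.02 to 2.78 CPM in the other posterior fossa tumours, and was lower without PF14 (-5.72 ± 0.36, edgeR adjusted p = 0.0022). PRDM16, a transcription factor also on chromosome 1, had -6.35 ± 0.80 (edgeR adjusted p = 0.0251). It is in none of the pairs, since no other protein-coding gene called lower with all 8 tumours lay under 500 kb from it. ADAMTS19 and MINAR2 on chromosome 5 lie 9.4 kb apart and had -8.51 and -6.87 (edgeR adjusted p = 0.0208 and 0.0423). KIF7 and TICRR on chromosome 15 overlap, so their reads may not be separable, and had -5.25 and -4.87 (edgeR adjusted p = 0.0296 and 0.0456); in all there were 8 such pairs under 500 kb apart.

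Chance position is argued against for the pairs of all 8 tumours, since 8 pairs of called protein-coding genes lay under 500 kb apart and 95% of 10000 random gene sets matched on expression gave 0 to 5 (permutation p = 0.0009). Shared reads of overlapping or abutting genes may account for the excess there, since 4 pairs at least 10 kb apart lay within the 0 to 4 of the random sets (permutation p = 0.0777). In the calls without PF14, tested later, 64 pairs of genes lower in posterior fossa tumours against 13 to 31 in sets also matched on gene density, and 51 pairs at least 10 kb apart against 12 to 29, argue against gene density and shared reads (permutation p = 0.0001 for both, the smallest possible). Extra copies of whole regions in supratentorial tumours were expected to lower the other genes nearby by 0.5 or more on the log2 scale. These lay at -0.14 (95% interval -0.35 to -0.02) from all genes, and -0.22 (-0.28 to -0.15) without PF14. Both fell short of the bound, with intervals on the negative side. The intervals come from resampling these nearby genes as if independent and do not cover the spread between tumours, so they may be too narrow. Copies in only some tumours or regions could lower this pooled median by less, so extra copies were not excluded. A regional difference in transcription or chromatin that goes with location or H3K27me3 stays open as a hypothesis and was not tested, and genes higher in posterior fossa tumours without PF14 gave 21 pairs against 5 to 20 (permutation p = 0.0178), or 13 against 5 to 19 at least 10 kb apart (permutation p = 0.311).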
